A study of Homo sapiens with 20 samples.

How the data were processed

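H3K27ac ChIP-seq was measured in primary human aortic endothelial cells, the cells that line the aorta, kept under disturbed or unidirectional flow for 24 hours. H3K27ac is an acetylation of histone H3 found at active promoters and enhancers. The series holds 20 samples: 10 H3K27ac samples, 5 per flow, and 10 input samples. The labels give the same cell lot for all samples, and the series' design text speaks of independent experiments. The lists thus stand for experiments on one lot of cells. The inputs have no summit list of their own and were not analysed here.

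Per the submitters' processing notes, Bowtie2, SAMtools, MACS2 and HOMER were used with the hg19 build. Versions, parameters, duplicate removal and the use of the inputs in peak calling are not given in the sources used here. The authors deposited 1 summit list per H3K27ac sample, so peaks were called per sample and not on pooled samples. Each line gives the position of a summit and a score. The score the authors deposited is read as the −log10 of a q-value, since the lowest value in each list lies just above 1.30, the −log10 of 0.05. Peak numbers run without gaps to the last line of each list, with 1 summit per peak. Read counts and signal were not used here, so sequencing depth is unknown. The number of summits per list stands in its place, and it limits which regions a list can show. A score depends on the depth of its library and was used to rank or filter summits within a list. Over lists, the highest score served only to break ties among named regions and to pick examples, so that choice favours the lists with high scores.

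Summits on the autosomes and chromosome X were used, from 756 to 73212 per list. Each summit was extended by 500 bp each way and overlapping intervals were merged over the 10 lists into regions. A list holds a region if at least 1 of its summits lies in it. Positions are hg19 and 1-based.

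List lengths differ many times, so single regions were tested under a Rasch model. In it the log odds that a list holds a region are a region term plus a list term. List terms were fitted by conditional maximum likelihood over all regions. Given how many lists hold a region, an exact conditional test, two-sided, asked how many of them were disturbed flow lists. Regions held by 2 to 8 lists were tested, with Benjamini-Hochberg adjustment and a threshold of 0.05. A call is relative to the rest of each list. The test takes the lists as independent given their list terms, so its p does not measure the spread between experiments. Tested on simulated data with 45311 regions and 200 changed ones, the test recovered 0% of regions with a log-odds shift of 4 and 11.0% of those with a shift of 8 after adjustment, with 0 false calls. At an unadjusted p under 0.05 it found 23.5% and 65.0% of them, and 1.63% and 1.55% of the unchanged regions. The simulated lists were drawn from the same model, so these rates need not hold for the real lists.

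Lists were also compared at equal length. The 5000 highest-scoring summits of each list were merged into regions, and the Jaccard index (shared regions over all regions of a pair of lists) was taken for every pair. The 9 lists with at least 5000 summits entered this comparison, 4 of disturbed and 5 of unidirectional flow. The difference between same-flow and different-flow pairs was tested by an exact permutation test, one-sided, over all 126 splits of the 9 lists. Single values per list were compared by exact permutation tests, two-sided, over the 252 labelled splits of 5 against 5 lists, where the smallest possible p is 0.00794.

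The tests and alternatives above, the rule for named regions and lists of genes were fixed before the data were examined. Named regions are the 10 per direction with the smallest conditional p, with ties broken by more holding lists and then by the highest score. Added after the data were seen were counts of regions that part the flows, a limma fit and exact tests on summits of the top 5000 in 100 kb windows, the same limma fit with list length as a covariate, and one on the full lists without it. Limma was run on log2(summits per 10000 + 1) with a mean-variance trend and Benjamini-Hochberg adjustment. In simulated data for the top 5000 summits, this fit recovered 3% of 200 windows changed 4-fold, with 0 false calls among 5406 windows. A limma fit in 100 kb windows of the full lists with list length as a covariate had been planned as an alternative. Like the other limma fits, it used the 9 lists with at least 5000 summits. In simulated data it recovered 16% of 200 windows changed 4-fold, with 0 false calls among 13460 windows. Counts in both limma simulations were independent Poisson draws, so these rates need not hold for the real lists. Other splits of the real lists gave up to 31 called windows in the top 5000 summits and up to 1 in the full lists. Other alternatives were a score of at least 5, extensions of 250 and 1000 bp, other top lengths, the replicate number as a block and leaving out each list in turn.

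Gene promoters, the fixed gene lists and motifs were planned but not analysed here. They need a gene annotation or sequence of hg19, and the gene table at hand is of another build, so regions are given by position without gene names. No 2 lists shared more than 0.808% of the shorter list's summits at the same base, so no list was treated as a copy of another. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, R 4.3.3 and limma 3.58.1.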

Results

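H3K27ac summits were compared between human aortic endothelial cells under disturbed flow, the irregular shear of arterial branch points and curves, and under unidirectional flow, the steady shear of straight arteries. Each flow had 5 lists, with replicate numbers 1 to 5. The disturbed flow lists held 61267, 23645, 37680, 756 and 65513 summits in the order of their replicate numbers. The unidirectional flow lists held 10024, 73212, 48754, 6822 and 12494. The longest list had 96.8 times as many summits as the shortest. Median scores ran from 2.94 in the shortest list, disturbed flow replicate 4, to 8.82 in disturbed flow replicate 1.

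The number of summits did not differ detectably with flow. Disturbed flow lists had 37772 ± 26886 summits and unidirectional flow lists 30261 ± 29417 (SD, n = 5 each). On the log10 scale the means were 4.29 ± 0.81 and 4.30 ± 0.45, a difference of -0.01 (exact permutation test, p = 0.984). Without disturbed flow replicate 4 the difference turned to 0.34 (exact permutation p = 0.198). The median scores averaged 6.21 ± 2.18 for disturbed and 5.73 ± 1.74 for unidirectional flow and were not tested, because a score follows the depth of its library.

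**Figure D1:**
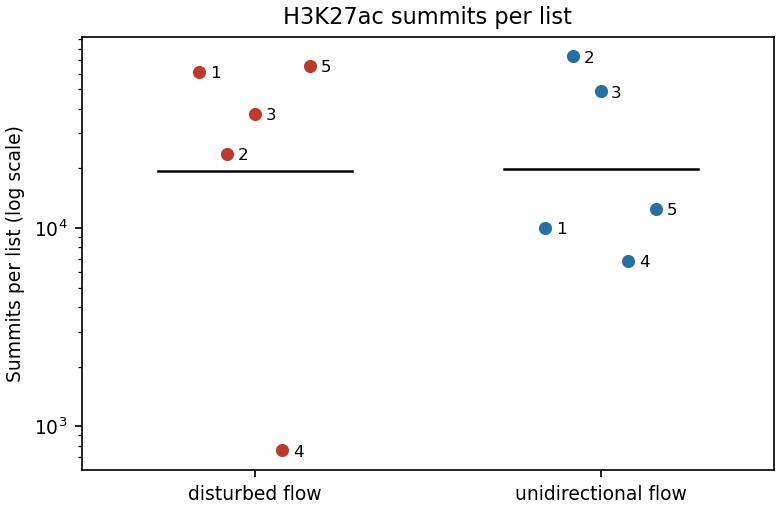
Summits per list on a log axis for disturbed flow (red) and unidirectional flow (blue). Points are single lists marked by replicate number and lines are geometric means. The lists range from 756 to 73212 summits, and both flows spread widely.

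All lists together formed 45311 regions of acetylated chromatin with a median width of 1635 bp. Of these, 11436 were held by 1 list and 514 by all 10. Regions held by more lists were wider, from a median of 1001 bp for those in 1 list to 3423 bp for those in all 10, a width that grows in part because more summits are merged. The widest region spanned 25140 bp on chromosome 1, from 22230077 to 22255216, and was held by 9 lists. The next widest lay on chromosome 9, from 124112396 to 124133392, and was held by 8 lists. The widest region held by all 10 lists lay on chromosome 1, from 100108952 to 100128918, and spanned 19967 bp. On average 84.7 ± 15.96% of the summits of a disturbed flow list and 89.5 ± 14.9% of those of a unidirectional flow list (SD, n = 5 each) lay in regions held by 5 or more lists. The difference of -4.79 percentage points was within the spread between lists (exact permutation p = 0.635). Without unidirectional flow replicate 2 or 3 it was -16.9 or -13.4 (exact permutation p = 0.286 and 0.349). The share was 100% in the shortest list and 64.6% in disturbed flow replicate 5, a list of 65513 summits.

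The strongest acetylated regions were shared more between lists of the same flow than between lists of different flow. Among the regions of the top 5000 summits, 2 disturbed flow lists had a mean Jaccard index of 0.489 ± 0.035 (SD over 6 pairs). For 2 unidirectional flow lists it was 0.457 ± 0.048 (SD over 10 pairs), and for lists of different flow 0.423 ± 0.040 (SD over 20 pairs). The same-flow pairs exceeded the different-flow pairs by 0.0462, more than any other split of these 9 lists, of which the highest gave 0.0363 (exact permutation p = 0.00794, the smallest this design allows). The mean index with its own flow was higher in 9 of 9 lists, by 0.0221 in unidirectional flow replicate 5 to 0.0737 in disturbed flow replicate 1. Over the full lists of all 10 samples, with disturbed flow replicate 4 added, the excess was 0.00855 and did not pass the test (exact permutation p = 0.270). Disturbed flow replicate 4 was too short to enter at 5000 summits. With all 10 lists trimmed to their top 500 summits, the excess was 0.0269 (exact permutation p = 0.00794).

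**Figure D2:**
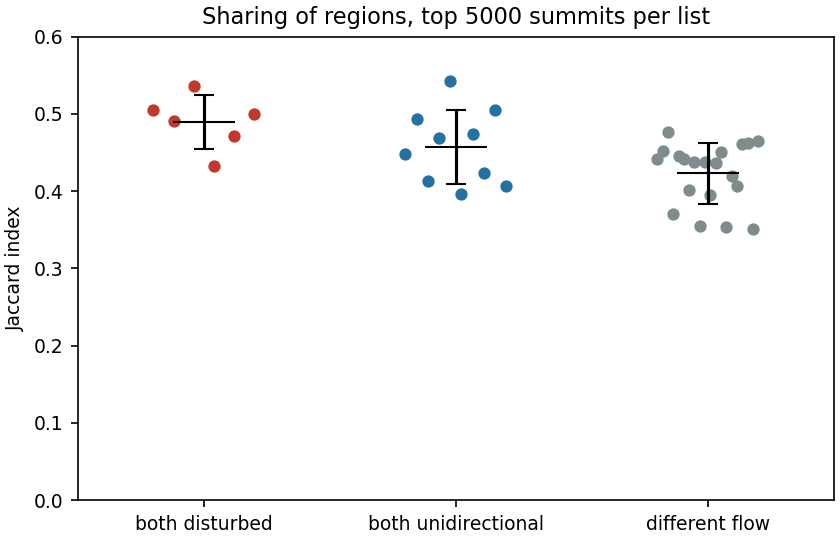
Jaccard index of regions from the top 5000 summits for pairs of lists. Points are pairs of lists, and black marks give the mean and SD over pairs, which share lists and are not independent. Means were 0.489, 0.457 and 0.423 for both disturbed, both unidirectional and different flow.

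The top 5000 summits gave 9407 regions, of which 997 were held by all 9 lists. Held by all 4 disturbed flow lists and none of the 5 unidirectional flow lists were 59 regions. Held by all 5 unidirectional flow lists and none of the 4 disturbed flow lists were 34. The 2 counts are not on one footing, since one needs 4 lists and the other 5. Together they made 93 regions, against a median of 10 and a highest value of 43 over 99 other splits of the 9 lists. At the top 2000 summits of the same 9 lists the counts were 22 and 20. They were 0 and 1 at the top 500 of all 10 lists, and 0 and 0 in all 10 full lists. These last 2 settings change the length and also add disturbed flow replicate 4, so the effects of the 2 changes cannot be told apart. The 3 highest-scoring on the disturbed flow side lay on chromosome 1 from 154126727 to 154127854, on chromosome 16 from 14725691 to 14727587, and on chromosome 9 from 35731293 to 35732394. On the unidirectional flow side they lay on chromosome 6 from 169571804 to 169573539, on chromosome 17 from 17614959 to 17617013, and on chromosome 16 from 21438643 to 21440392. These 6 were named after their values were seen. None of the 93 regions was absent from every full list of the other flow. Of the 59, 28 had a summit in 4 full unidirectional flow lists, and of the 34, 28 had one in 4 full disturbed flow lists. Without disturbed flow replicate 2 or 3 the disturbed flow side had 111 or 116 regions, and without unidirectional flow replicate 2, 4 or 5 the unidirectional flow side had 53, 57 or 56. The regions differed in whether they ranked among the top 5000 of a list, and ranks come from lists of different full length.

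**Figure D3:**
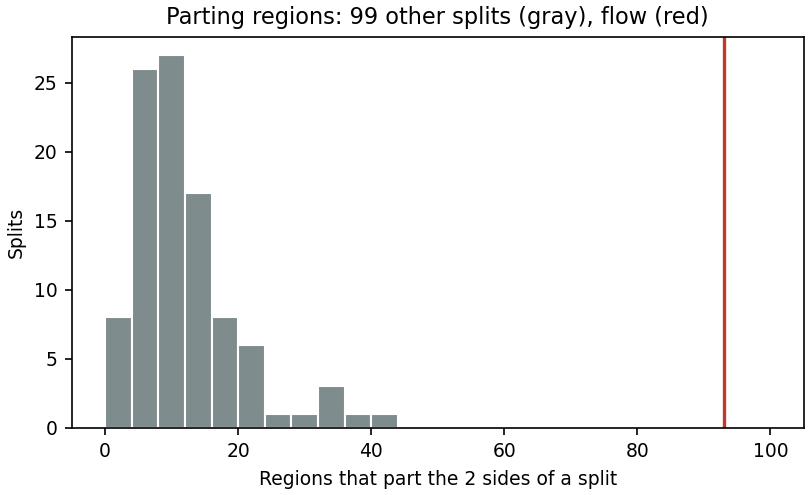
Number of regions held by every list on one side of a split and none on the other, among the top 5000 summits. The gray histogram shows 99 other splits of the 9 lists, none above 43, and the red line marks the 93 regions of the split by flow.

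Some windows of 100 kb held more of a list's 5000 highest-scoring summits under unidirectional flow. These counts follow ranks within lists of different full length and do not measure how much acetylation a window carries. Of the 10 windows of 100 kb with the most top summits over all 9 lists, 2 passed the exact permutation test after Benjamini-Hochberg adjustment over these 10, and both had more under unidirectional flow. On chromosome 1, from 235100001 to 235200000, there were 4.0 ± 0.82 summits per 5000 under disturbed and 10.2 ± 2.17 under unidirectional flow (SD, n = 4 and 5, adjusted exact p = 0.040). On chromosome 3, from 171500001 to 171600000, there were 6.75 ± 1.71 and 11.2 ± 1.304 (adjusted exact p = 0.040). In a limma fit with list length as a covariate, adjusted over the same 10, the window on chromosome 1 passed (limma adjusted p = 0.016) and the one on chromosome 3 did not (limma adjusted p = 0.121). Over all windows limma called the one on chromosome 1 without list length (limma adjusted p = 0.036) but not with it (limma adjusted p = 0.108), and the one on chromosome 3 in neither fit. The lists of the 2 flows did not overlap in either window, and the unadjusted p of 0.00794 was the smallest that 4 against 5 lists can give. The window with the most top summits, on chromosome 17 from 75100001 to 75200000, had 6.25 ± 1.26 and 13 ± 3.08 summits and missed the threshold (adjusted exact p = 0.053). The window on chromosome 12 from 96800001 to 96900000 had 5.75 ± 0.50 and 9.4 ± 2.88 (adjusted exact p = 0.060). Windows on chromosome 19 from 45900001 to 46000000 and on chromosome 1 from 156000001 to 156100000 had 10.0 ± 2.00 and 8.75 ± 1.71 summits under disturbed flow. Under unidirectional flow they had 9.0 ± 1.58 and 8.2 ± 1.304, differences within the spread between lists (adjusted exact p = 0.573 and 0.683).

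**Figure D4:**
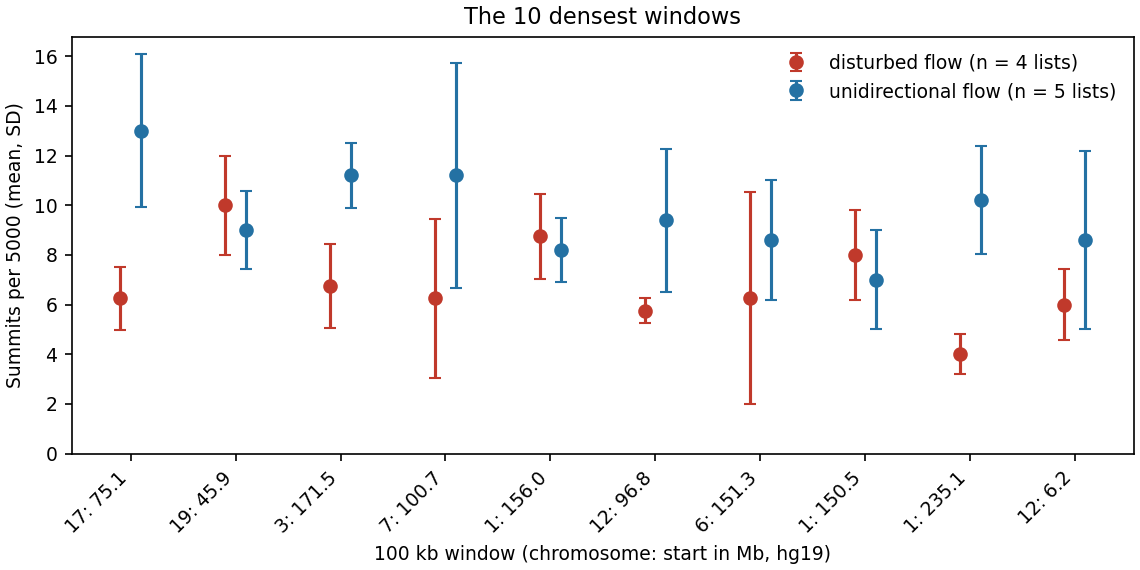
Summits among the top 5000 of a list in the 10 windows of 100 kb that held the most, by disturbed flow (red, 4 lists) and unidirectional flow (blue, 5 lists). Points are means and bars SDs, and windows are named by chromosome and start in Mb. The windows that start at 171500001 on chromosome 3 and at 235100001 on chromosome 1 passed the adjusted exact test, which has no list length term.

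Over all 5982 windows that held a top summit, limma called 71 at an adjusted p under 0.05, 37 with more top summits under disturbed and 34 under unidirectional flow. With list length as a covariate it called 62, of which 59 were among the 71, 38 on the disturbed and 24 on the unidirectional flow side. In 58 of the 71 no list of the other flow had a top summit, and the lists of the flow that held them averaged 1 to 2.4 top summits. The remaining 13 held summits in both flows, 10 with more under unidirectional and 3 under disturbed flow, and 2 of the 13 stayed past the threshold with list length as a covariate. Among these 13 were windows on chromosome 8 from 124400001 to 124500000, with 1.25 ± 0.50 summits under disturbed and 4.4 ± 1.14 under unidirectional flow, and on chromosome 5 from 151000001 to 151100000, with 2.0 ± 0 and 5.0 ± 1.22 (SD, n = 4 and 5, limma adjusted p = 0.015 and 0.029, or 0.081 and 0.095 with list length). On chromosome 7, from 134300001 to 134400000, there were 0.25 ± 0.50 and 2.8 ± 0.84 (limma adjusted p = 0.021, or 0.088 with list length). On the disturbed flow side, the window on chromosome 2 from 54600001 to 54700000 had 2 top summits in each of 4 lists and none under unidirectional flow (limma adjusted p = 0.000196, or 0.00246 with list length). The SD was 0 in both flows there, as in other called windows. Such a limma p rests on the variance shared across windows and does not measure spread between these lists. An exact test of 4 against 5 lists cannot give a p below 0.00794. Windows on chromosome 9 from 131100001 to 131200000 and on chromosome 8 from 130800001 to 130900000 each had 1.75 ± 0.50 top summits and none under unidirectional flow (limma adjusted p = 0.000815 for both, or 0.00647 and 0.00598 with list length). In their full lists, unidirectional flow replicates 1, 2, 3 and 5 had summits in the parting region of each of these windows. On the unidirectional flow side, chromosome 9 from 91300001 to 91400000 had 1.8 ± 0.45 top summits and none under disturbed flow (limma adjusted p = 0.000815, or 0.00598 with list length). Disturbed flow replicates 1, 2, 3 and 5 had summits in its parting region in their full lists. With only windows that averaged at least 1 summit per list, 7 were called, 1 on the disturbed and 6 on the unidirectional flow side. Without disturbed flow replicate 2 the sides had 66 and 39 windows, and without disturbed flow replicate 3 they had 70 and 34. In the full lists of the same 9 samples, without disturbed flow replicate 4, limma with list length as a covariate called 0 of 14430 windows. Of these windows, 1196 had an unadjusted limma p under 0.05, and without that covariate limma called 5.

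In the full lists 30923 regions could be tested one by one, and 1 passed the threshold. It lay on chromosome 2, from 160797881 to 160800081, and was held by unidirectional flow replicates 1, 2, 3 and 5 and by no disturbed flow list, against an expected 2.27 disturbed flow lists among 4 (exact conditional test, adjusted p = 0.048). With summits extended by 250 bp each way 11 regions passed, and with 1000 bp or the top 5000 summits 0 did. Near the region on chromosome 2, the next cluster of summits toward higher positions was present in every list except disturbed flow replicate 4. The call on chromosome 2 was lost without disturbed flow replicate 1, 2, 3 or 5 or without unidirectional flow replicate 1, 3 or 5, with adjusted exact p from 0.064 to 0.731. It was also lost with a score of at least 5, where the adjusted exact p was 1 and the region on chromosome 13 from 111595503 to 111597417 passed in its place (adjusted exact p = 0.019). At an unadjusted p under 0.05 there were 603 regions on the disturbed and 409 on the unidirectional flow side, 3.27% of those tested. Without unidirectional flow replicate 2, there were 26 regions on the disturbed and 430 on the unidirectional flow side, and without unidirectional flow replicate 3 there were 198 and 193. Without disturbed flow replicate 3 there were 261 and 139. With a score of at least 5 there were 395 and 875. The conditional p depends only on how many lists of each flow hold a region, so regions with equal counts share it. In the main fit, those held by 3 disturbed and no unidirectional flow lists had an unadjusted exact conditional p of 0.034. Whole sets of regions can thus cross 0.05 together when list terms change, and the counts per side do not measure a balance between flows. In simulated data 1.63% of unchanged regions had an unadjusted exact conditional p under 0.05. Those were drawn from the fitted model with independent lists, so 1.63% is not a chance rate for the real lists. Another split of the 10 real lists gave 1038 such regions, against 1012 for the split by flow.

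The other regions named on the unidirectional flow side did not pass the threshold (adjusted exact conditional p = 0.220 to 0.366). Held by 4 unidirectional flow lists and 1 disturbed flow list were regions on chromosome 9 from 84488701 to 84490977, chromosome 18 from 5454989 to 5457911, chromosome 8 from 124478192 to 124480039, and chromosome 7 from 98639848 to 98641560. So were regions on chromosome 13 from 111595503 to 111597417, chromosome 18 from 57540323 to 57542161 and chromosome 3 from 83272637 to 83274329. Held by all 5 unidirectional flow lists and by disturbed flow replicates 1 and 5 were a region of 6556 bp on chromosome 5, from 138777630 to 138784185, and one on chromosome 1 from 218546979 to 218549046, the 2 highest-scoring of 7 regions held by as many lists of each flow. The region on chromosome 8 lies in the window that limma called among the top summits.

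On the disturbed flow side no region passed the threshold (adjusted exact conditional p = 0.430 for all 10 named). The test does not treat the 2 sides evenly, because the list terms differ. A region held by 4 disturbed and no unidirectional flow lists had an unadjusted exact conditional p of 0.00207. The reverse pattern, on chromosome 2, had 1.55e-06. The lack of calls here is thus not a comparison with the 1 call on the unidirectional flow side. Held by all 5 disturbed flow lists and by unidirectional flow replicates 2 and 3 were regions on chromosome 20 from 35088718 to 35092335, chromosome 12 from 52345114 to 52346366, and chromosome 5 from 121296635 to 121298948. Each of these includes a summit of score 2.94 in disturbed flow replicate 4. Without that list each was held by 0.208 disturbed flow lists more than expected, in place of 1.06 (adjusted exact p = 1). Held by disturbed flow replicates 1, 2, 3 and 5 and by no unidirectional flow list were regions on chromosome 10 from 112216758 to 112220263, chromosome 7 from 37289479 to 37291841, chromosome 7 from 114627354 to 114629370, and chromosome 17 from 26391927 to 26393773. So were regions on chromosome 15 from 62433636 to 62434764, chromosome 15 from 63999810 to 64001321 and chromosome 10 from 30825844 to 30827569. These 7 are the highest-scoring of 82 regions held by 4 disturbed flow lists and no unidirectional flow list, all with the same p.

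**Figure D5:**
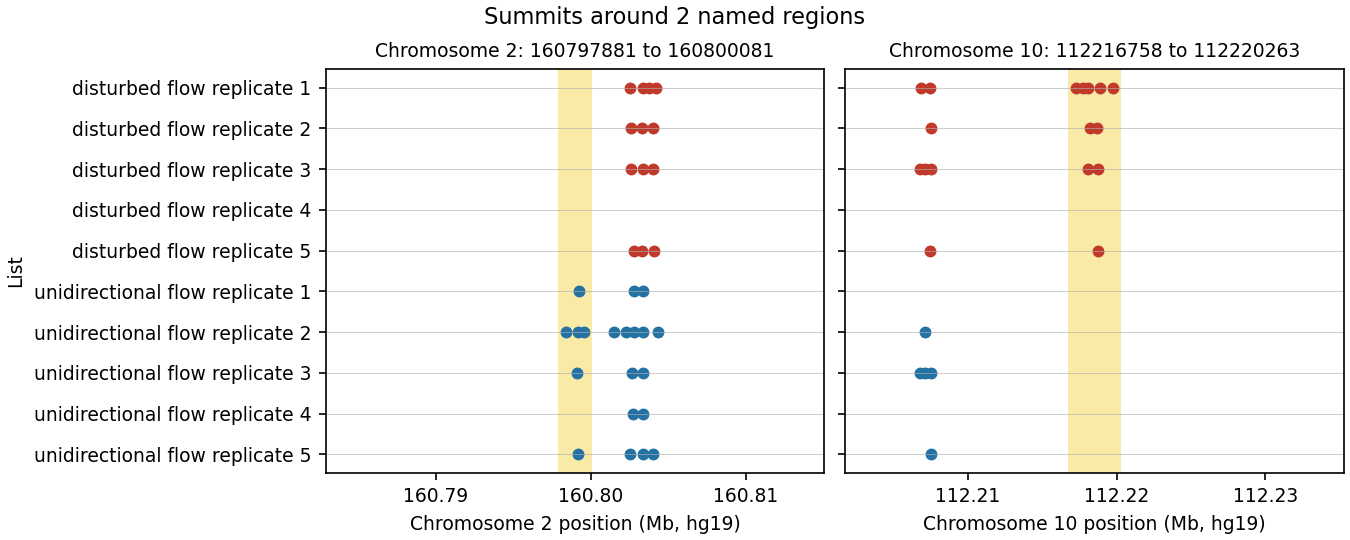
Summits of each list around a region held only by unidirectional flow lists (left, chromosome 2) and one held only by disturbed flow lists (right, chromosome 10), with hg19 positions in Mb. Points are summits, red for disturbed and blue for unidirectional flow, and shading marks the region. The shaded region on chromosome 2 holds summits of 4 unidirectional flow lists, and the one on chromosome 10 of 4 disturbed flow lists.

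No difference between the flows was detected in how summits were spread over the chromosomes, but the test had little reach. The smallest possible exact p, 0.00794, is too large for a single autosome to pass after adjustment over 22. None of 22 autosomes passed the exact permutation test after adjustment, and 1 had an unadjusted p under 0.05. That was chromosome 5, with 4.98 ± 0.66% of autosomal summits under disturbed and 5.50 ± 0.11% under unidirectional flow (SD, n = 5 each, exact permutation p = 0.032, adjusted p = 0.611). Disturbed flow replicate 4 had 3.85%. Chromosome 1 held the most, with 10.5 ± 0.81% and 10.2 ± 0.28% (exact permutation p = 0.611).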

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

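The tests of a background source, of another cell type and of equal length were set before their results were seen, and the test of exchanged labels after. Of the 52 groups of values checked for a far sample, 14 were flagged, where chance flags about 1 in 20 groups, or 2.6. In 13 of the 14, disturbed flow replicate 4 stood apart from the other 4 disturbed flow lists. Among these flags 12 were chromosome shares of the same list. Such shares depend on each other, so they are not separate events to set against 2.6. The log10 number of summits of disturbed flow replicate 4 was 2.88. Its shares of autosomal summits were 11.95% on chromosome 1, 4.91% on 3, 3.85% on 5, 3.32% on 6, 5.58% on 9, 5.31% on 10 and 6.64% on 11. They were 1.59% on chromosome 13, 5.31% on 14, 2.92% on 15, 7.44% on 19 and 3.72% on 20. Disturbed flow replicate 3 stood apart with 1.87% on chromosome 18.

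The tables argue against random background as the source of this short list. Of its 756 summits, 96.7% lay in regions that at least 8 of the other 9 lists hold (exact 95% binomial interval 95.2 to 97.8%). Another cell type cannot be told apart: 94.4% lay in regions held by all of the other 8 lists, against 94.6% of as many top summits of the next shortest list, unidirectional flow replicate 4, but both are near the ceiling and no list of another cell type was used here. Exchanged labels in replicate 4 are argued against, since the unidirectional flow list shares more with its own flow, by 0.0523. With every list at its top 756 summits, the short list had a mean Jaccard index of 0.287 with disturbed and 0.254 with unidirectional flow lists. When the other disturbed flow lists were trimmed to 756 summits, 0 of the 12 chromosome shares stood apart, in that no gap to the nearest list was above the 95% limit for the range of the 5 lists, although 5 of the 12 lay outside the range of the other 4. This is consistent with a list that shows mainly the strongest regions. Whether low depth or weak enrichment made it short stays open, because read counts were not analysed here, and no biological reason for its length was tested.

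Summits on the mitochondrial chromosome, which the comparisons leave out, appeared in 2 lists: 19 in unidirectional flow replicate 2 and 7 in disturbed flow replicate 3.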

How the results depend on the processing

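Settings for regions that part the flows and for 100 kb windows of the top 5000 summits were chosen after seeing the data, as was the fit of the full lists without list length. So were the counts at an unadjusted p under 0.05 with the top 5000 summits, with the replicate block and with other limits on the holding lists. Whether the replicate numbers mark pairs is not settled. The correlation of same-numbered lists after group means were removed ran from -0.38 to 0.11, and 1 of 5 lists correlated best with its own number. The value of -0.38 was that of replicate 4, which includes the shortest list. In Jaccard index, different-flow pairs with the same number exceeded those with different numbers by 0.0205. With the replicate block the excess of same-flow over different-flow Jaccard index stayed at 0.0462, but its exact p was 0.0625, the smallest that block allows. The block gave 4 regions past the adjusted threshold in place of 1, 458 in place of 603 regions at an unadjusted p under 0.05 on the disturbed and 42 in place of 409 on the unidirectional flow side, and 35 windows in place of 71, of which 24 were among the 71.

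The excess in Jaccard index was 0.0405 to 0.0526 with a list left out and kept its call. Over the full lists, with disturbed flow replicate 4 added, it was 0.00855 and lost it. The difference in log10 list length was -0.14 to 0.34 with a list left out, and changed sign without disturbed flow replicate 4 (0.34), unidirectional flow replicate 2 (0.13) or 3 (0.09). As plain numbers the difference was 7511 summits. Regions past the adjusted threshold numbered 0 to 1 with a list left out, 11 with 250 bp each way and 0 with 1000 bp, with the top 5000 summits or with regions held by 1 to 9 lists. Limma in 100 kb windows, run without disturbed flow replicate 4, gave 0 over the full lists with list length as a covariate and 5 without it. It gave 71 over the top 5000 summits without list length and 62 with it. Counts at an unadjusted p under 0.05 were 26 to 812 (disturbed flow) and 139 to 587 (unidirectional flow) with a list left out, 395 and 875 with a score of at least 5, and 102 and 160 with the top 5000 summits. Regions that part the flows numbered 59 to 116 and 34 to 57 with a list left out, and 22 and 20 with the top 2000 summits. With disturbed flow replicate 4 added, they numbered 0 and 1 with the top 500 of all lists, and 0 and 0 over all full lists. The windows numbered 77 to 105 with a list left out, 49 at 200 kb and 7 with a mean of at least 1 summit. With the top 2000 summits there were 32, of which 6 were among the 71. The highest counts come from leaving out disturbed flow replicate 2 (105) or 3 (104 windows and 116 regions). Autosomes past the threshold stayed at 0, where a single autosome could not have passed even at the smallest possible p. The reproducibility difference ran from -16.9 to -1.82 percentage points, without a call. For the region on chromosome 2 from 160797881 the adjusted exact p ran from 0.014 with the replicate block to 1 with a score of at least 5, with no value at 1000 bp. Of 279 values of named regions under other settings, 268 kept direction and call. Only the region on chromosome 2 had a call in the main fit, and the 8 values that lost a call are all its own. For the other named regions, keeping the call meant staying short of the threshold, whatever the change in size, and tied regions repeat the same values. The region on chromosome 5 from 138777630 to 138784185 turned to 0.17 disturbed flow lists above expectation with a score of at least 5. Except where fewer lists or summits enter by construction, the cause was not tested. Promoters, gene lists, promoter shares and motifs were not run, for want of an hg19 annotation. List length limits what a short list can show.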

Other observations

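Tests of list length, of the 4 longest lists, of the replicate number and of chance for the single regions were chosen after the result was seen; those of chance for parting regions and windows and of clustering were set before theirs.

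Pairs of parting regions of the same direction lay close together at 3 places. On the disturbed flow side they spanned 15632 bp on chromosome 2, from 54642661 to 54658292, and 47147 bp on chromosome 9, from 125764883 to 125812029. On the unidirectional flow side they spanned 22961 bp on chromosome 9, from 134531081 to 134554041. A hypothesis is that flow may act on stretches longer than 1 region. In all, 6 of the 93 regions had a neighbour of the same direction within 100 kb, against a median of 0 and a 95% limit of 4 in 10000 random draws of regions held by as many lists (one-sided permutation p = 0.014). The excess rests on 3 pairs. The draws matched how many lists hold a region, not which ones. Nearby regions held by the same lists for any reason could also give an excess, so this test cannot decide on the hypothesis.

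The greater sharing of top regions within a flow was weighed against list length. After the Jaccard index was regressed on the difference and sum of the log10 lengths of each pair, the same-flow excess was 0.0481, and 1 split of the 9 lists, the real one, gave as much, with 0.0351 the highest other. Among the 4 longest lists, the 2 same-flow pairs averaged 0.540, which is 0.0625 above the highest different-flow pair (0.477). Different-flow pairs with the same replicate number exceeded those with different numbers by 0.0205. Each number occurs once per flow, so a shared experiment can only raise different-flow pairs, and this value does not bear on the source of the same-flow excess of 0.0462. The labels give no library or sequencing batch, so a batch that follows flow stays open beside flow itself, as does the depth of the libraries, which was not analysed here.

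For the number of parting regions, 1 of 100 splits, the real one, gave as many (93, highest other 43). For the windows of the top 5000 summits it was again 1 of 100 (71, highest other 31). Both counts were added after the data were seen, though their tests of chance were set before the results of those tests. They draw on the same top 5000 summits as the Jaccard index, where the real split also ranked first. Many called windows contain a parting region. The 2 counts are thus not independent results and add no separate evidence against chance. For the number of regions at an unadjusted p under 0.05, 2 of 100 splits gave as many as the real 1012. The other one gave 1038 and differs from the real split by an exchange of the 2 lists of replicate 4. That test was chosen after the result was seen, and the count hung on single lists. Without unidirectional flow replicate 2 it was 26 on the disturbed and 430 on the unidirectional flow side. Chance is therefore not called excluded for this count. Nor can chance be excluded for the 1 region past the adjusted threshold, where 8 of 100 splits gave as many, up to 2. For the full lists with list length the splits decide nothing, since 0 windows were called and 100 of 100 splits must then give as many (highest other 1).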
